A study of Homo sapiens with 23 samples.

How the data were processed

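THP-1 monocytic cells, THP-1 macrophages made with PMA and macrophages polarised with LPS and IFN-γ were compared by RNA sequencing, with 3 samples per group, and macrophages given 300 nM of EXOSC10 siRNA with macrophages given control siRNA, with 3 samples per group. Monocytic cells and macrophages were also compared by whole-genome bisulfite sequencing, with 1 library each. The 3 samples of M2 macrophages and the nanopore samples were not analysed here. The labels do not say whether the samples of a group are separate differentiations. The p-values therefore measure only the spread between these samples, which may be technical.

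The expression values were, per the submitters' processing notes, made by base calling with CASAVA 1.8, alignment with STAR 2.5.2a to GRCh38 and counting with featureCounts 1.5.0-p3. The deposited log2 values are regularised log values that the authors made with DESeq2 1.22.2, which draw genes with few reads towards their mean over all libraries, so that changes of weakly expressed genes are understated. The deposited table gave no read counts, so the depth per library is unknown. The retained fraction in the deposited intron tables was made with IRFinder, per the file headers, whose version is not stated. It is the depth of an intron divided by the sum of that depth and the spliced reads, which held within 0.01 in 92.7%, 93.2% and 94.3% of the introns of the 3 tables. The counts of spliced reads and the coverage depth of each intron in the deposited intron tables are pooled over the samples of a group, while the fractions are also given per sample. The p-values in the deposited tables are one-sided, the smaller of both directions, and come from the pooled reads, so they hold no spread between samples. Introns marked as not tested by the authors were left out of the adjusted p-values. The tables of macrophages were made with strand-aware counting and that of the knockdown without it, per the file headers. Each listed intron had all 3 samples of one group above the other and a pooled fraction of at least 0.01 in either group, which was checked on the files. The methylation file as deposited holds counts of methylated reads and the coverage of 28269977 CpG sites. Its aligner and methylation caller are not given in the sources used here. Its positions run beyond the ends of 14 GRCh38 chromosomes, and 1.73% of its chromosome 22 positions are CG in GRCh38, against 1.62% of all positions, so its build is not GRCh38.

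Expression was tested with limma 3.58.1 in R 4.3.3, with the data.table package 1.17.8, on the deposited log2 values, with a variance trend and all 8 libraries in the model. Genes with a mean of at least 1 over the libraries were tested (25205 of 28853), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The deposited column of polarised replicate 1 held the same values as that of macrophage replicate 1 and was counted once, as a macrophage, a choice made after the values were seen. In the intron table polarised replicate 1 differs from macrophage replicate 1. Among the 28853 identifiers 28466 had a symbol in GENCODE 44, and 548 of 570 genes of 35 lists written before the data were examined were found. Lists with at least 5 tested members were tested with camera in limma at a preset correlation of 0.01, with the correlation estimated per list as an alternative, and with fry, which asks whether the genes of a list move on balance one way. Named genes were chosen by a rule set before the data were examined. It takes the 5 largest rises and falls with an adjusted p under 0.05, no overlap between the groups and a mean of at least 8 in either group, and up to 3 called genes per list with the largest change. EXOSC10 was named as the target. Some genes that the rule selects are not reported here.

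Introns were called at an adjusted p under 0.05 from the authors' deposited p-values, with a difference of at least 0.1 in the pooled fraction and a fraction of at least 0.1 in either group. In the knockdown table the adjusted p alone was used. Introns with a warning in both groups would have been left out, but there were 0. Named introns were the 6 largest rises and the 6 largest falls of the pooled fraction among called introns, with 1 per gene, a rule set before the data were examined. A further 6 per direction, with at least 100 spliced reads in both groups and no warning, were chosen after the values were seen. As an alternative, limma was run on the arcsine square roots of the fractions per sample. Those p-values are too small, because the listed introns were selected for separated groups. Intron numbers, flanking sequence and the siRNA site were taken from GENCODE 44 and GRCh38 with pysam 0.24.0 and samtools 1.23.1. All listed introns matched an annotated intron exactly, and 98.8%, 98.9% and 98.8% of them had GT and AG ends. Features and correlations were tested two-sided with 100000 permutations, and gene lists with 10000 random lists matched on expression. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and statsmodels 0.14.6, and plots matplotlib 3.10.9.

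Methylation levels were computed at autosomal CpG sites with at least 10 reads in both libraries, as methylated reads over all reads, with Wilson 95% intervals. These intervals cover counting error only. Sites were compared with Fisher's exact test, two-sided, at an adjusted p under 0.05 and a difference of at least 25 percentage points, and bins of 10 kb with at least 10 sites at a difference of at least 20 points. Promoter windows and retained introns were not joined to methylation, since the builds differ and no conversion between them was at hand. The bins took the place of the promoters. As no bin was called, the bins named come from those with a difference of at least 10 points and were chosen after the values were seen.

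The tests were run on simulated data. With 200 changed genes among 25205 in noise of the size measured, limma recovered 48.5%, 58.2% and 95.5% of log2 changes of 0.5, 1 and 2 in the design of macrophages against monocytic cells, with 9 false calls. In the design of polarised against resting macrophages it recovered 34.8%, 53.7% and 94.0%, with 3 false calls. For the intron tables only the adjustment of p-values was run, on 8000 simulated p-values of which 200 were set very small. It recovered 100% of the 200 with 21 false calls. That checks the arithmetic and not how well the authors' p-values find changed introns. With shifts far larger than the simulated noise, limma on simulated fractions recovered 100% of 200 with 3 false calls in 3000. Fisher's test recovered 100% of 200 bins with a difference of 30 points, with 0 false calls in 20000 bins.

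Alternatives were a fit with the replicate number as a block, a fit on the libraries of each comparison alone, no variance trend, median centring, quantile normalisation, filters at a mean of 5 and none, a log2 change of at least 1, each library left out in turn, and 9 or 7 columns in place of 8. For introns they were differences of 0.05 and 0.2, an unadjusted p under 0.05, no warnings, at least 20 reads in both groups, limma on the fractions, a doubled p and an adjusted p under 0.01. For methylation they were coverage minimums of 5 and 20, all chromosomes, an upper coverage limit at the 99th percentile (106 reads in both libraries), the mean over sites and bin differences of 10 points. Leaving out a polarised library leaves 1 in that group, which is then assumed to vary like the other groups.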

Results

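RNA sequencing, intron retention and whole-genome bisulfite data were collected from THP-1 cells, an established human leukaemia line that grows as monocytic cells and differentiates into adherent macrophages on treatment with the phorbol ester PMA. The series held 23 samples. Poly(A) RNA libraries were given for monocytic cells, for macrophages and for macrophages polarised with lipopolysaccharide (LPS) and interferon gamma (IFN-γ), with 3 samples per group. A separate experiment compared 3 macrophage samples given a control siRNA with 3 given an siRNA against EXOSC10, the catalytic nuclear subunit of the RNA exosome that degrades RNA from its 3′ end. Whole-genome bisulfite sequencing, which reads methylated cytosines as C and unmethylated ones as T, had 1 library of monocytic cells and 1 of macrophages. The questions were how expression, the retention of introns in spliced RNA and CpG methylation differed between the cell states, and how introns responded to loss of EXOSC10.

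The expression values covered 28853 genes in 9 columns and carried no read counts, so the depth behind each value is unknown; the labels give only a planned depth. The column for polarised macrophage replicate 1 equalled the column for macrophage replicate 1 in all 28853 genes. It differed from the other 2 polarised columns with an SD of 0.954 and 0.958 on the log2 scale, while the pairs of the other columns of one group differed with an SD of 0.298 to 0.395. That column was therefore counted once, as a macrophage sample, which left 8 libraries, with n = 3 monocytic, n = 3 macrophage and n = 2 polarised samples. The intron tables hold reads spliced across each intron, with medians of 566 in macrophages and 543 in monocytic cells, and the bisulfite libraries covered each autosomal CpG site used by 32.1 and 32.8 reads on average.

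Macrophages differed from monocytic cells in the expression of granule, proliferation, macrophage, lysosome and interferon-stimulated genes. Of the genes of the cell cycle and DNA replication list, 25 of 25 fell, with a median log2 change of −2.26, and 14 of 16 genes of myeloid progenitors and granules fell, with a median of −1.90. Among type I interferon-stimulated genes, 27 of 27 rose (median 3.20), as did 21 of 26 macrophage markers (median 2.78) and 21 of 22 AP-1 and immediate early genes (median 2.36). Among genes with a mean value of at least 8 in either group, the rise reached 31.9-fold for VWF, which encodes the clotting factor carrier von Willebrand factor. The largest fall among them was that of MS4A3, a gene of granulocyte and monocyte progenitors, which fell by 6.32 on the log2 scale.

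Under limma, 16409 of the 25205 genes tested changed at an adjusted p under 0.05, of which 8646 were higher and 7763 lower in macrophages, and 6505 changed at least 2-fold on the log2 scale of the table. Quantile normalisation of the libraries, which moved the median log2 change of all genes from 0.03 to −0.10, turned the excess to 7614 higher and 9347 lower. VWF (ENSG00000110799, chromosome 12, 5948877 to 6124770, minus strand, GRCh38) stood at 12.28 ± 0.04 in macrophages and 7.28 ± 0.03 in monocytic cells (log2 units, SD, n = 3 each; limma adjusted p = 1.52e-13). EMP1, an epithelial membrane protein gene on chromosome 12 (13196723 to 13219941), rose from 12.15 ± 0.02 to 17.09 ± 0.04 (SD, n = 3 each; limma adjusted p = 1.52e-13). The other largest rises among such genes were those of ATP2B2, a plasma membrane calcium pump gene (4.95 ± 0.07, log2 change ± SE), the actin regulator gene WIPF3 (4.88 ± 0.10) and the homeobox gene DLX3 (4.87 ± 0.06). MS4A3 (ENSG00000149516, chromosome 11, 60056587 to 60071115, plus strand) fell from 10.20 ± 0.14 to 3.87 ± 0.27 (SD, n = 3 each; limma adjusted p = 2.76e-11). The serine protease inhibitor genes SERPINB10 (−5.46 ± 0.17) and SERPINB2 (−5.32 ± 0.13), F13A1, the A chain of clotting factor XIII (−5.27 ± 0.15), and the T cell receptor gamma constant gene TRGC1 (−5.19 ± 0.16) fell next. In each of these 10 genes every library of one group lay beyond every library of the other, which the naming rule required.

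The granule genes that fell included CTSG, the neutrophil protease cathepsin G (−3.81 ± 0.10), and MPO, myeloperoxidase (−3.67 ± 0.24). Of the 16 genes 0 rose (camera adjusted p = 2.62e-07; adjusted p = 0.114 with an estimated correlation). The macrophage markers that rose included MERTK, a receptor for apoptotic cells (4.69 ± 0.05), SPP1, osteopontin (4.61 ± 0.06), and the scavenger receptor MSR1 (4.50 ± 0.05). Another 3 markers fell (camera adjusted p = 2.98e-08; adjusted p = 0.114 with an estimated correlation). RRM2, a ribonucleotide reductase subunit (−2.85 ± 0.05), CDC45 of the replicative helicase (−2.74 ± 0.08) and TYMS, thymidylate synthase (−2.64 ± 0.07), led the fall of the cell cycle genes. That list had a camera adjusted p of 1.48e-16 (adjusted p = 0.114 with an estimated correlation). EGR2 (4.58 ± 0.05) and the early response gene IER3 (4.16 ± 0.05) led the immediate early genes. In that list 1 gene fell (camera adjusted p = 1.31e-11; adjusted p = 0.114 with an estimated correlation). Of 23 lysosome genes 22 rose and 0 fell, with a median of 1.16 (camera adjusted p = 3.34e-10; adjusted p = 0.184 with an estimated correlation). The proton pump subunit gene ATP6V0D2 (4.44 ± 0.08), the acid lipase LIPA (2.85 ± 0.05) and cathepsin B, CTSB (2.85 ± 0.06), rose most.

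Interferon and inflammatory genes were higher in macrophages before any polarising stimulus. The type I interferon-stimulated genes IFI6 (4.33 ± 0.07), IFI44L (4.08 ± 0.06) and OAS3, an antiviral oligoadenylate synthetase (4.07 ± 0.05), were the leading members of their list (camera adjusted p = 1.22e-17; adjusted p = 0.0816 with an estimated correlation). Of 21 IFN-γ target genes, 16 rose, with a median of 1.27 (camera adjusted p = 1.62e-05; adjusted p = 0.114 with an estimated correlation). They included BATF2 (5.68-fold) and the complement inhibitor gene SERPING1 (2.40 ± 0.12), whereas IRF8, a transcription factor of the monocyte lineage, fell (−2.28 ± 0.05). Of 25 inflammatory cytokine and chemokine genes 20 rose and 1 fell, with a median of 1.20 (camera adjusted p = 1.03e-05; adjusted p = 0.114 with an estimated correlation). The macrophage growth factor CSF1 (4.37 ± 0.05), EBI3 (2.85 ± 0.13) and IL1B, interleukin 1 beta (2.71 ± 0.05), rose most. Of 18 NF-kB feedback and target genes 13 rose and 2 fell, with a median of 0.84 (camera adjusted p = 0.00023; adjusted p = 0.101 with an estimated correlation). ICAM1, a cell adhesion receptor, rose by 3.29 ± 0.04 and BCL3 by 2.02 ± 0.06. MHC class I presentation genes rose in 14 of 17 cases and fell in 1, with a median of 0.63 (camera adjusted p = 0.000399; adjusted p = 0.354 with an estimated correlation). HLA-E rose by 2.06 ± 0.07 and the peptide transporter TAP1 by 1.52 ± 0.05. Of 9 MHC class II genes 2 rose, among them HLA-DMB (2.24 ± 0.24), and 4 fell, among them HLA-DQB1 (−1.03 ± 0.25). The median of this list was −0.29 and the mean 0.15 (camera adjusted p = 0.677). Alternative activation markers rose in 10 of 15 cases and fell in 2, with a median of 1.34 (camera adjusted p = 0.00526; adjusted p = 0.141 with an estimated correlation). The transglutaminase gene TGM2 rose by 3.62 ± 0.05 and the interleukin 1 receptor antagonist gene IL1RN by 3.10 ± 0.05, while F13A1, named above, had the largest change of the list, a fall (−5.27 ± 0.15).

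Genes of RNA processing and translation were mostly lower in macrophages. Of 28 core spliceosome genes 24 fell and 1 rose, with a median of −0.59 (camera adjusted p = 2.58e-06; adjusted p = 0.28 with an estimated correlation). The Sm protein genes SNRPF (−1.34 ± 0.10), SNRPE (−1.24 ± 0.09) and SNRPD1 (−1.21 ± 0.08) fell most. Of 19 hnRNP genes, which encode nuclear RNA-binding proteins, 16 fell and 0 rose, with a median of −0.49 (camera adjusted p = 1.62e-05; adjusted p = 0.181 with an estimated correlation). HNRNPA2B1 stood at −1.02 ± 0.06 and HNRNPA1 at −0.92 ± 0.06. SR proteins, splicing factors rich in arginine and serine, and their kinases fell in 13 of 19 cases and rose in 2, with a median of −0.47 (camera adjusted p = 0.00184; adjusted p = 0.28 with an estimated correlation). The kinase gene SRPK1 changed by −1.24 ± 0.05 and SRSF1 by −1.03 ± 0.05. Among 19 genes of the RNA exosome and its cofactors 13 fell and 2 rose, with a median of −0.36 (camera adjusted p = 0.00528; adjusted p = 0.28 with an estimated correlation). The subunit genes EXOSC3 (−1.25 ± 0.06), EXOSC2 (−1.18 ± 0.05) and EXOSC8 (−0.93 ± 0.07) fell most. EXOSC10 itself (ENSG00000171824, chromosome 1, 11066618 to 11099869, minus strand) fell from 12.59 ± 0.14 to 12.13 ± 0.08 (SD, n = 3 each; limma adjusted p = 0.000144). Of 10 nonsense-mediated decay genes 6 fell and 0 rose (median −0.20), and the list did not pass (camera adjusted p = 0.0504). UPF3B (0.501-fold) fell most, and UPF3A, another gene of this pathway, fell by 0.47 ± 0.04. Of 15 snoRNA host genes 11 fell and 1 rose, with a median of −0.57 (camera adjusted p = 0.00121; adjusted p = 0.488 with an estimated correlation). DANCR stood at −2.18 ± 0.09 and SNHG1 at −1.28 ± 0.05. Cytoplasmic ribosomal protein genes fell in 28 of 30 cases (median −0.50), with RPS19 at −0.85 ± 0.12 (camera adjusted p = 1.29e-05; adjusted p = 0.511 with an estimated correlation). Mitochondrially encoded transcripts fell in 13 of 13 cases (median −0.75), with MT-ND5 at −1.40 ± 0.13 (camera adjusted p = 1.48e-05; adjusted p = 0.181 with an estimated correlation).

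Of 14 p53 target genes 11 rose and 0 fell (median 0.75), with the cell cycle inhibitor CDKN1A at 2.94 ± 0.07 and TP53INP1 at 2.34 ± 0.06 (camera adjusted p = 0.00023; adjusted p = 0.128 with an estimated correlation). Unfolded protein response genes rose in 8 of 12 cases and fell in 2 (median 0.74), with the chaperone gene DNAJB9 at 1.64 ± 0.06 (camera adjusted p = 0.0266; adjusted p = 0.624 with an estimated correlation). Oxidative phosphorylation genes fell in 14 of 23 cases and rose in 3 (median −0.33), with ATP5PO at −0.66 ± 0.11 and COX5B at 0.59 ± 0.11 (camera adjusted p = 0.0377; adjusted p = 0.708 with an estimated correlation). That call ended without monocytic replicate 1 (adjusted p = 0.0959), macrophage replicate 1 (0.0509) or macrophage replicate 3 (0.0751). Of 16 glycolysis genes 9 fell, among them LDHA, lactate dehydrogenase (−2.02 ± 0.06), and 5 rose, among them the hexokinase gene HK1 (1.06 ± 0.06), with a camera adjusted p of 0.23 and a median of −0.39. DNA methylation machinery genes went both ways, with a median of −0.03 (camera adjusted p = 0.491). Of the 11 genes 4 fell, among them UHRF1, which recruits the maintenance methyltransferase (−3.09 ± 0.05), and the demethylase gene TET1 (−2.68 ± 0.15). Another 3 rose, among them the methyltransferase gene DNMT3A (1.28 ± 0.05). Of 6 NADPH oxidase genes 4 rose, such as CYBB (2.03 ± 0.04), and 1 fell (median 1.26, camera adjusted p = 0.0659). This list passed without monocytic replicate 1 (adjusted p = 0.0436) and under quantile normalisation (0.0488), as did nonsense-mediated decay (0.0204 and 0.0242). Cholesterol synthesis genes rose in 9 of 17 cases and fell in 5 (median 0.18, and −0.03 under quantile normalisation; camera adjusted p = 0.44). The lanosterol synthase gene LSS fell by 1.76 ± 0.07 and MSMO1 rose by 1.26 ± 0.06. Cholesterol efflux genes rose in 3 of 8 cases, such as APOE, a lipoprotein component (4.33 ± 0.07), and the transporter ABCA1 (1.75 ± 0.07), and fell in 3 (median 0.29, and −0.05 under quantile normalisation; camera adjusted p = 0.674).

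Markers of other cell types moved in the same samples. Of 7 osteoclast markers 7 rose, with a median of 3.72 (camera adjusted p = 2.47e-05; adjusted p = 0.101 with an estimated correlation). The fusion gene DCSTAMP (4.47 ± 0.05), ATP6V0D2, which is also in the lysosome list, and the acid phosphatase gene ACP5 (3.99 ± 0.10) rose most. Of 8 dendritic cell markers 6 rose, such as CCR7 (1.93 ± 0.11), and 1 fell (median 0.95, camera adjusted p = 0.0679, and 0.0491 under quantile normalisation). Of 5 B cell markers PAX5 (1.94 ± 0.09) and CD79A (0.89 ± 0.15) rose and 2 fell (camera adjusted p = 0.833). Lists with fewer than 5 tested members had no test as a list. Of T cell markers 2 of 2 rose, with CD3D at 1.47 ± 0.23, and of fibroblast markers 3 of 3 rose, with the collagen gene COL1A1 at 3.01 ± 0.14. Among the fibroblast markers the call of PDGFRB ended under quantile normalisation, with the replicate block and without monocytic replicate 2 or 3 or macrophage replicate 2 or 3. Of the rest, 1 of 2 epithelial markers rose (CLDN4, 0.71 ± 0.22), and 1 of 3 megakaryocyte and erythroid markers rose (ITGA2B, 0.47 ± 0.16) while 1 fell (GP9, −0.86 ± 0.18). The call of ITGA2B ended under quantile normalisation and without monocytic replicate 1, macrophage replicate 1 or macrophage replicate 3. Counts adjusted over the list alone were the same as those over all genes except for lysosome (23 rose, 0 fell), MHC class I (14 and 2), oxidative phosphorylation (3 and 15), RNA exosome (3 and 13) and hnRNP genes (2 and 16). Of 31 lists tested with camera 22 passed, and 0 passed with an estimated correlation. Under fry, which does not compare a list with the other genes, 9 more lists passed. Only 1, oxidative phosphorylation, lost its call (fry adjusted p = 0.0995). In splits of the same libraries that mixed the groups, camera at the preset correlation still passed 16 to 21 lists. Each of those splits sets more monocytic libraries against fewer, and so keeps part of the group difference. Their counts therefore cannot show how often that test passes without a difference. As 0 lists passed with an estimated correlation, a pass at the preset correlation alone is weak evidence.

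**Figure D1:**
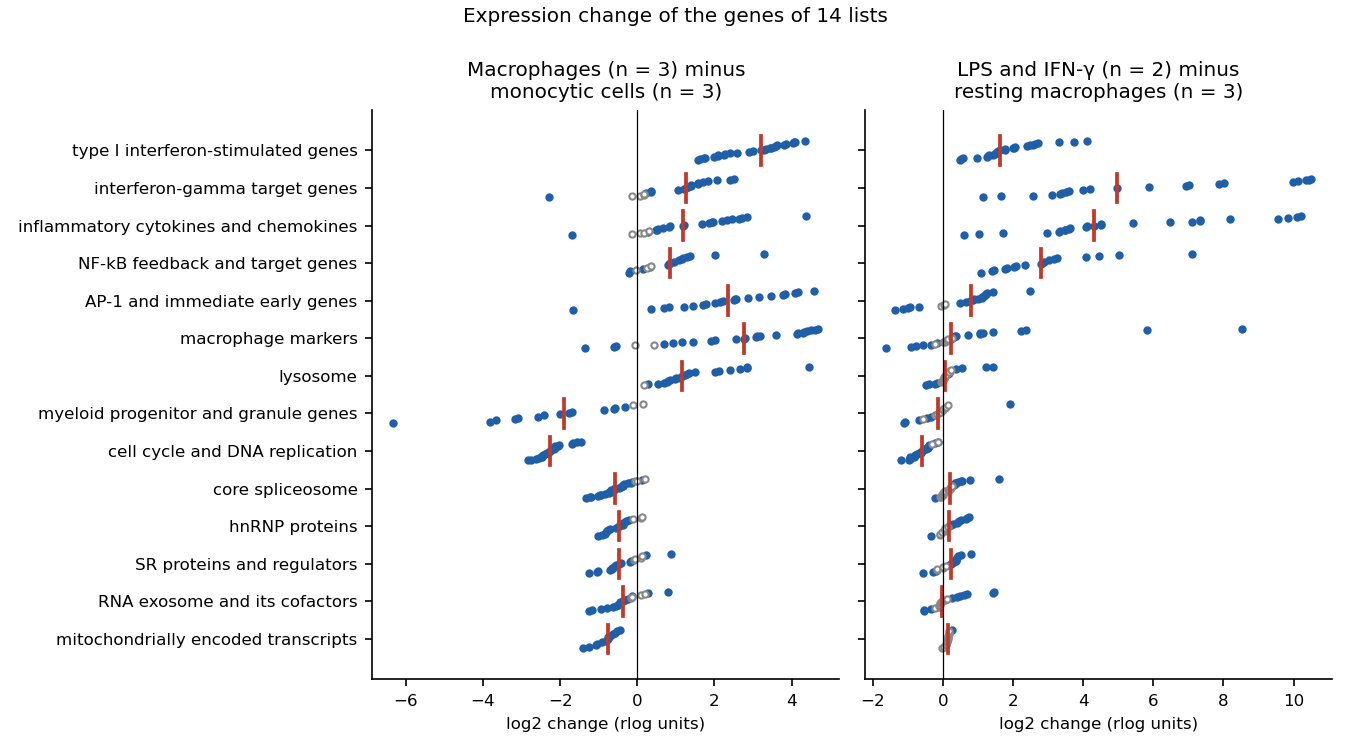
Log2 change of each tested gene of 14 lists, macrophages minus monocytic cells at the left and LPS and IFN-γ polarised minus resting macrophages at the right; filled points passed an adjusted p of 0.05, open points did not, and red lines are list medians. The medians of type I interferon-stimulated genes lie at 3.20 and 1.61, and those of cell cycle genes at −2.26 and −0.59; the small medians of the core spliceosome (0.20) and hnRNP (0.17) genes at the right turned negative under quantile normalisation, as did those of macrophage markers, lysosome, SR and mitochondrially encoded genes.

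Polarisation of macrophages with LPS and IFN-γ raised chemokine, cytokine and interferon target genes. All tested members rose in 4 lists: 25 of 25 inflammatory cytokine and chemokine genes (median log2 change 4.32), 21 of 21 IFN-γ target genes (median 4.97), 18 of 18 NF-kB genes (median 2.81) and 27 of 27 type I interferon-stimulated genes (median 1.61). Among genes with a mean value of at least 8 in either group, ACOD1, which makes the antimicrobial metabolite itaconate, rose 1439.9-fold, and the T cell chemoattractant CXCL9 rose by 10.43 ± 0.06 on the log2 scale. Cell cycle genes, already lower in macrophages than in monocytic cells, fell in 23 of 25 cases (median −0.59).

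Under limma 13326 of 25205 genes changed, 6372 higher and 6954 lower in polarised macrophages, an excess that turned under median centring (6919 higher, 6579 lower) and grew under quantile normalisation (5540 higher, 8076 lower). Of them 4074 changed at least 2-fold. Quantile normalisation moved the median log2 change of all genes from −0.04 to −0.11. With the repeated column kept as a polarised sample, limma called 0 genes, while 7534 had an unadjusted p under 0.05. ACOD1 (ENSG00000102794, chromosome 13, 76948511 to 76958638, plus strand) stood at 15.57 ± 0.16 in polarised (SD, n = 2) and 5.08 ± 0.22 in resting macrophages (SD, n = 3; limma adjusted p = 1.06e-12). CXCL9 (ENSG00000138755, chromosome 4, 76001275 to 76007509, minus strand) rose from 9.11 ± 0.08 (SD, n = 3) to 19.54 ± 0.05 (SD, n = 2; limma adjusted p = 2.47e-15). IDO1, which degrades tryptophan (10.37 ± 0.09), and the chemokine genes CCL8 (10.21 ± 0.09) and CXCL11 (10.12 ± 0.06) followed. The largest falls among genes with a mean of at least 8 in either group were those of the adenosine receptor gene ADORA1 (−2.90 ± 0.22), the secreted glycoprotein gene STC2 (−2.83 ± 0.08), LRRC25 (−2.76 ± 0.12), ULBP1, a ligand of a natural killer cell receptor (−2.43 ± 0.13), and CHAC1, a glutathione-degrading enzyme of the stress response (−2.35 ± 0.12). In each of these 10 genes every library of one group lay beyond every library of the other, which the naming rule required. EXOSC10 stood at 12.26 ± 0.03 (SD, n = 2), a log2 change of 0.13 ± 0.08 from resting macrophages (limma adjusted p = 0.203).

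The cytokine genes IL6 (10.10 ± 0.21) and CCL2, a monocyte attractant (9.85 ± 0.11), the signalling adaptor TRAF1 (7.10 ± 0.06) and the antiviral genes IFIT2 (4.12 ± 0.05) and RSAD2 (3.75 ± 0.05) were among the rises. The camera adjusted p was 1.54e-22 for cytokines, 2.05e-23 for IFN-γ targets, 1.74e-16 for NF-kB genes and 3.5e-20 for type I interferon-stimulated genes, and these lists also passed with an estimated correlation (adjusted p = 0.0128, 0.0128, 0.00798 and 0.0159). MHC class I genes rose in 16 of 17 cases, with a median of 1.00 and a camera adjusted p of 5.79e-09 (adjusted p = 0.283 with an estimated correlation). TAP1 rose by 3.33 ± 0.06 and the transactivator gene NLRC5 by 1.72 ± 0.05. MHC class II genes rose in 7 of 9 cases, with a median of 2.94 (camera adjusted p = 0.000339; adjusted p = 0.0574 with an estimated correlation). Their transactivator CIITA rose by 4.46 ± 0.16 and HLA-DRA by 4.44 ± 0.25. Alternative activation markers rose in 10 of 15 cases and fell in 0, with a median of 0.98 (camera adjusted p = 0.00132; adjusted p = 0.135 with an estimated correlation). The chemokine genes CCL13 (6.80 ± 0.29) and CCL18 (3.06 ± 0.15) and the lectin gene CLEC10A (5.74 ± 0.23) rose most. Immediate early genes rose in 14 of 22 cases, such as the phosphatase gene DUSP5 (2.48 ± 0.06), and fell in 5, among them FOS (−1.36 ± 0.06). Their median was 0.81 (camera adjusted p = 0.00201; adjusted p = 0.584 with an estimated correlation). CDC20, an activator of the anaphase ubiquitin ligase (−1.20 ± 0.09), and AURKA, a mitotic kinase (−0.97 ± 0.05), led the fall of cell cycle genes (camera adjusted p = 1.59e-08; adjusted p = 0.294 with an estimated correlation). Cholesterol synthesis genes fell in 11 of 17 cases and rose in 3 (median −0.34), at a camera adjusted p of 0.0249 (adjusted p = 0.61 with an estimated correlation). DHCR7 (0.4996-fold) and the squalene synthase gene FDFT1 (−0.67 ± 0.08) were among the falls and LSS among the rises (0.67 ± 0.08).

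Lists of RNA processing and metabolism moved little, and several changed sign with the scaling. Of 19 hnRNP genes 10 rose and 1 fell (median 0.17), with HNRNPM at 0.73 ± 0.07, whereas quantile normalisation gave 4 rises, 10 falls, a median of −0.22 and a camera adjusted p of 0.402 in place of 0.0141 (adjusted p = 0.584 with an estimated correlation). Core spliceosome genes rose in 11 of 28 cases and fell in 1 (median 0.20), with PRPF3 at 1.60 ± 0.05, and in 4 and 8 under quantile normalisation (median −0.05). The camera adjusted p was 0.0199 (adjusted p = 0.701 with an estimated correlation), 0.0596 without polarised replicate 3 and 0.984 under quantile normalisation. Glycolysis genes rose in 10 of 16 cases and fell in 1 (median 0.33), with the glucose transporter SLC2A1 at 1.40 ± 0.06, and in 5 and 7 under quantile normalisation (median −0.08, camera adjusted p = 0.812 in place of 0.00409; adjusted p = 0.6 with an estimated correlation). Of 10 nonsense-mediated decay genes 7 rose, such as SMG1 (1.40 ± 0.12), and 1 fell (median 0.31, camera adjusted p = 0.0412), a call that ended without macrophage replicate 2 (adjusted p = 0.055) and under quantile normalisation (0.0831), with an adjusted p of 0.254 with an estimated correlation. Ribosomal protein genes rose in 4 of 30 cases (median 0.17, camera adjusted p = 0.0608), passed as higher without macrophage replicate 2 (adjusted p = 0.0192) or polarised replicate 2 (0.017) and under median centring (11 rose, adjusted p = 0.0176), and fell in 25 under quantile normalisation (median −0.31, adjusted p = 0.000224). Oxidative phosphorylation genes rose in 3 and fell in 2 of 23 cases (median 0.06, camera adjusted p = 0.505), and fell in 11 under quantile normalisation (median −0.21, adjusted p = 0.0419). Of 19 genes of the RNA exosome and its cofactors 7 rose, such as EXOSC9 (1.45 ± 0.05) and RBM7 (1.43 ± 0.09), and 4 fell, with a median of −0.04 and a mean of 0.18 (camera adjusted p = 0.412). SR proteins and their kinases rose in 11 of 19 cases, such as TRA2A (0.80 ± 0.06), and fell in 3, such as SRPK2 (−0.58 ± 0.06), with a median of 0.23, or −0.07 under quantile normalisation (camera adjusted p = 0.0835, and 0.0375 under median centring).

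The remaining lists did not pass in the main fit. Macrophage markers rose in 13 of 26 cases, led by the complement genes C1QB (8.52 ± 0.20) and C1QC (5.83 ± 0.23), and fell in 6. Their median was 0.23, or −0.08 under quantile normalisation (camera adjusted p = 0.119). Granule genes rose in 1 of 16 cases (CEBPE, 1.90 ± 0.14) and fell in 5, such as the cytokine receptor gene FLT3 (−1.11 ± 0.06; median −0.15, camera adjusted p = 0.289). Lysosome genes rose in 7 of 23 cases, such as cathepsin S, CTSS (1.43 ± 0.06), and fell in 4 (median 0.05, camera adjusted p = 0.24), with 17 falls under quantile normalisation (median −0.27, adjusted p = 0.0419). NADPH oxidase genes rose in 2 of 6 cases, CYBB (1.59 ± 0.05) and NCF1 (1.42 ± 0.09), and fell in 2, among them RAC2 (−0.48 ± 0.07; median 0.03, or −0.18 under quantile normalisation; camera adjusted p = 0.655). Cholesterol efflux genes rose in 2 of 8, such as ABCG1 (1.04 ± 0.37), and fell in 4, such as SCARB1 (−0.61 ± 0.06; median −0.27, camera adjusted p = 0.24). The call of ABCG1 ended with the replicate block. Of 15 snoRNA host genes 3 rose and 2 fell (median 0.08, or −0.08 under quantile normalisation; camera adjusted p = 0.533). Among 11 DNA methylation genes 4 rose, such as DNMT3L (1.52 ± 0.43), and 6 fell, such as DNMT3B (−1.22 ± 0.09; median −0.15, camera adjusted p = 0.43). Of 14 p53 targets 3 rose, such as the death receptor gene FAS (3.79 ± 0.08), and 5 fell, such as TP53INP1 (−1.34 ± 0.07). The list had a median of −0.06 and a mean of 0.06 (camera adjusted p = 0.533). Of 12 unfolded protein response genes 7 rose, such as XBP1 (0.94 ± 0.08), and 5 fell, led by CHAC1, named above, and TRIB3 (0.249-fold), with a median of 0.29, a mean of −0.21 and a quantile-normalised median of −0.12 (camera adjusted p = 0.734). Of 13 mitochondrially encoded transcripts 1 rose (median 0.13, camera adjusted p = 0.24), and 8 fell under quantile normalisation (median −0.37). Among markers of other cells, dendritic cell genes rose in 3 of 8 cases, LAMP3 (8.36 ± 0.09), CCR7 (5.97 ± 0.12) and CLEC9A (4.58-fold), and fell in 1 (median 0.06, or −0.07 under quantile normalisation; camera adjusted p = 0.24). PAX5 rose by 3.46 ± 0.10 and was the only 1 of 5 B cell markers to rise, with 1 that fell (camera adjusted p = 0.869). Among 2 T cell markers IL7R rose (2.42 ± 0.06). Osteoclast markers rose in 3 of 7 cases, such as OCSTAMP (1.27 ± 0.09), and fell in 2, among them ATP6V0D2 (−0.39 ± 0.09; median −0.02, or 0.01 under median centring; camera adjusted p = 0.536). Of 3 megakaryocyte and erythroid markers 1 fell, of 3 fibroblast markers 2 fell, and of 2 epithelial markers CLDN4 fell (−1.42 ± 0.24). Counts adjusted over the list alone differed for macrophage markers (15 rose, 7 fell), cell cycle (0 and 24), lysosome (6 and 4), efflux (2 and 5), glycolysis (12 and 1), oxidative phosphorylation (0 and 1), ribosomal proteins (0 and 0), RNA exosome (7 and 5), SR proteins (11 and 5), mitochondrially encoded transcripts (0 and 0), megakaryocyte (1 and 1) and fibroblast markers (0 and 3). Of 31 lists tested 14 passed with camera and 4 with an estimated correlation.

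Most introns in the authors' deposited table had a lower retained fraction in macrophages than in monocytic cells. The retained fraction is the share of transcripts at an intron that keep it. Of the 8543 introns in the authors' deposited table, 6254 (73.2%, Wilson 95% interval 72.3% to 74.1%) had a lower retained fraction in macrophages, where the median over listed introns was 0.0232 against 0.0337 in monocytic cells. The Wilson intervals of such shares of introns treat introns as independent, though they share genes and libraries, and hold no spread between samples. An intron in DGAT1, the enzyme of the last step of triglyceride synthesis, was retained at 0.169 ± 0.009 in macrophages and 0.450 ± 0.004 in monocytic cells (SD, n = 3 each). In ARSA, the lysosomal arylsulfatase A gene, an intron was retained at 0.114 ± 0.013 and 0.381 ± 0.049 (SD, n = 3 each). In the authors' pooled values the depth of the DGAT1 intron was 434.9 in macrophages and 1540.7 in monocytic cells. That of the ARSA intron was 280.0 and 286.5, with 2095 and 404 spliced reads, so its lower fraction came with more spliced reads at a similar depth. Introns that rose included 1 in PAXBP1, from 0.260 ± 0.036 to 0.547 ± 0.054, and 1 in THOC6, a gene of the mRNA export complex THO, from 0.105 ± 0.009 to 0.285 ± 0.044 (SD, n = 3 each). The pooled depth of the PAXBP1 intron was 289.5 in macrophages and 207.7 in monocytic cells, with 232 and 569 spliced reads. For THOC6 the depth was 273.4 and 249.3, with 683 and 2143 spliced reads, so that rise came mostly with fewer spliced reads.

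An adjusted p under 0.05 from the p-values of the authors' deposited table, a difference of at least 0.1 and a fraction of at least 0.1 in either group left 577 introns in 440 genes, of which 85 were higher and 492 lower in macrophages. On the fractions of the libraries limma called 823 introns, 230 higher and 593 lower. Every listed intron had all 3 libraries of one group above the other, which chance gives for 10% of unselected introns, and the count fell to 309 (47 higher, 262 lower) without introns that carry a coverage warning. The lower introns had a median GC content of 59.7%, against 52.9% in the higher ones (permutation p = 2e-05) and 50.4% in those not called. Their median lengths were 275.5 and 294.0 bases (permutation p = 0.726), against 762.5 bases in introns not called. These permutations treat introns as independent, though some share a gene. Calls needed a fraction of at least 0.1, far above the median of listed introns, so contrasts with introns not called also compare more with less retained introns. The DGAT1 intron is number 14 of 16 (chromosome 8, 144317110 to 144317186, between coding exons), with 2141 spliced reads in macrophages and 1879 in monocytic cells in the authors' deposited table (adjusted p = 1.01e-82). The ARSA intron is number 2 of 7 (chromosome 22, 50627053 to 50627165; adjusted p = 1.33e-42 from the authors' deposited table). The 3′ UTR intron of TMEM41B, an endoplasmic reticulum protein (intron 7 of 7, chromosome 11, 9281042 to 9283370), fell from 0.862 ± 0.009 to 0.526 ± 0.037 (SD, n = 3 each). It belongs to a transcript other than the canonical one and is marked as overlapping a known exon in the authors' deposited table. Reads there need not come from a retained intron. Its pooled depth was 1046.0 in macrophages and 746.0 in monocytic cells, with 935 and 121 spliced reads. An intron of ITGA7, an integrin subunit (number 5 of 24, chromosome 12, 55698918 to 55699869), fell from 0.469 ± 0.096 to 0.173 ± 0.006 (SD, n = 3 each). Its pooled depth was 167.2 in macrophages and 170.7 in monocytic cells, with 789 and 189 spliced reads. The PAXBP1 intron is number 6 of 17 (chromosome 21, 32759270 to 32759776) and that of THOC6 number 4 of 12 (chromosome 16, 3026167 to 3026250; adjusted p = 4.09e-28 from the authors' deposited table). An intron of the dynein chain gene DYNC1LI2 (number 7 of 12, chromosome 16, 66730224 to 66732338) rose from 0.249 ± 0.030 to 0.501 ± 0.060 (SD, n = 3 each). These introns were chosen after their values were seen, for having at least 100 spliced reads in both groups and no warning.

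Of the introns with the largest differences, several rest on few reads. Among the 6 largest rises, NPR2 had 7 and 15 spliced reads in macrophages and monocytic cells in the authors' deposited table, ADCY4 28 and 11, ZNF491 7 and 13, LAMP5 5 and 1264, UNC13D 22 and 22 and PAXBP1 232 and 569. Among the 6 largest falls, TOB1 had 22 and 0 spliced reads, NEB 19 and 0, AC004754.3 13 and 1, MC1R 65 and 1 and TMPRSS9 128 and 5 in the authors' deposited table. PPM1M, a protein phosphatase gene whose expression rose by 3.26 on the log2 scale, had 1091 and 7 spliced reads in the authors' deposited table, and its intron 1 of 9 was retained at 0.236 ± 0.035 against 0.810 ± 0.077 (SD, n = 3 each).

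**Figure D2:**
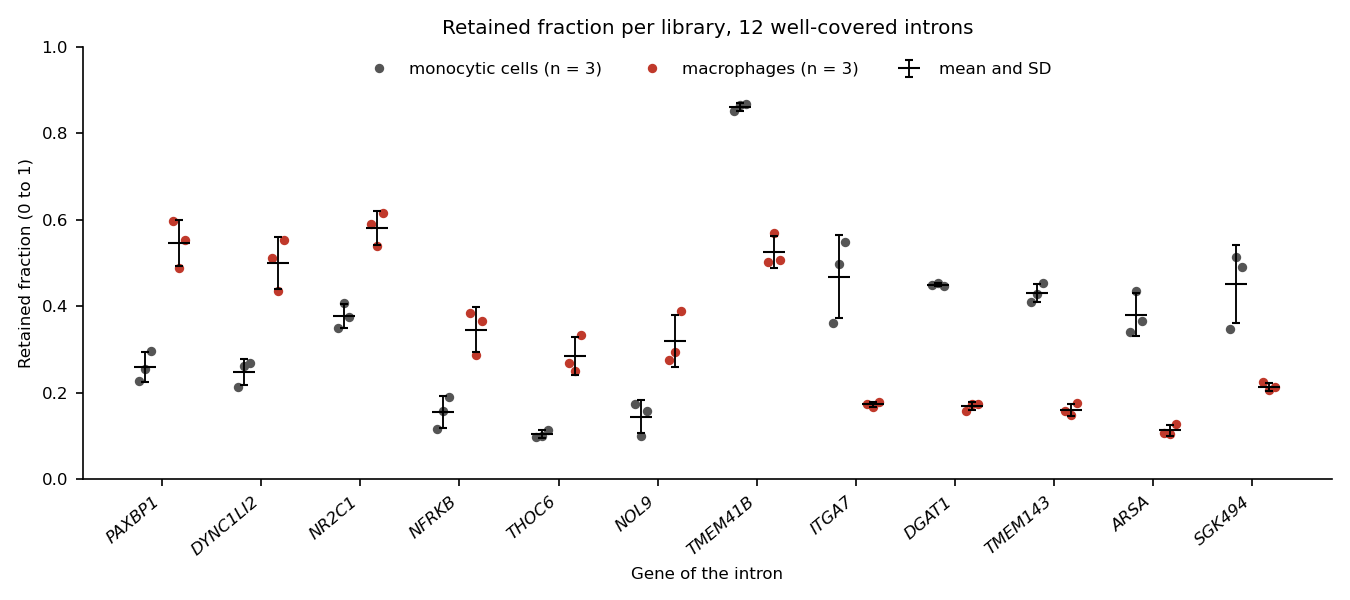
Retained fraction, from 0 to 1, of 12 introns with at least 100 spliced reads in both groups and no warning, the 6 with the largest rise and the 6 with the largest fall; points are libraries (3 per group), bars are means with SD. The introns of PAXBP1, DYNC1LI2, NR2C1, NFRKB, THOC6 and NOL9 lie higher in macrophages and those of TMEM41B, ITGA7, DGAT1, TMEM143, ARSA and SGK494 lower, with no overlap between the groups. Only introns without overlap were listed, so that separation was fixed by the selection.

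Retention and expression were compared across genes with a called intron. Over 436 genes the change in retained fraction and the log2 expression change had a Spearman rho of −0.143 (permutation p = 0.00288, 0.00576 adjusted over 2 relations) and a Pearson r of −0.184 (permutation p = 0.00013). Genes are not independent replicates, and over all 4319 genes with a tested intron rho was −0.02 (permutation p = 0.174). Among the 366 genes with a lowered intron 185 rose in expression and 101 fell, with a median log2 change of 0.22, above 100% of 10000 random gene lists matched on expression, 95% of which lay between −0.12 and 0.05. Spliced reads are part of the denominator of the fraction, so added spliced reads alone lower it, which the random lists do not account for. Over all listed introns 70.3% were lower in genes that rose and 74.6% in genes that fell. Among the 70 genes with a raised intron 19 rose and 33 fell, with a median of −0.12, at percentile 19.4 of random lists.

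In polarised against resting macrophages, introns changed in both directions. Of the 6832 introns in the authors' deposited table, 3594 (52.6%, Wilson interval 51.4% to 53.8%) were lower after LPS and IFN-γ. An intron of KPTN, a component of a complex that regulates mTOR signalling, rose from 0.195 ± 0.031 to 0.606 ± 0.030, and 1 of C19orf66, an interferon-induced antiviral gene, rose from 0.242 ± 0.017 to 0.496 ± 0.012 (SD, n = 3 each). The last intron of CXCL2, a neutrophil attractant, fell from 0.212 ± 0.026 to 0.0264 ± 0.0038 (SD, n = 3 each). The PAXBP1 intron named above fell from 0.547 ± 0.054 to 0.276 ± 0.022 (SD, n = 3 each). The macrophage libraries are the same in both comparisons.

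The same thresholds left 368 introns in 283 genes, 214 higher and 154 lower, from the p-values of the authors' deposited table, whereas limma on the fractions of the libraries called 613, of which 291 were higher and 322 lower. Introns that rose were shorter than those that fell (medians 218.5 and 406.5 bases, permutation p = 3e-05) and richer in GC (60.4% and 52.1%, permutation p = 1e-05, the smallest value that 100000 permutations can give). The permutations treat introns as independent, though some share a gene. Against monocytic cells, introns lower in the same macrophage libraries were also richer in GC (59.7%, and 52.9% in higher ones). A GC bias of those shared libraries was not told apart from an effect of polarisation. The KPTN intron is number 6 of 11 (chromosome 19, 47480408 to 47480759; adjusted p = 3.08e-18 from the authors' deposited table). That of C19orf66 is number 6 of 7 (chromosome 19, 10091354 to 10091475; adjusted p = 2.04e-44 from the authors' deposited table) and that of CXCL2 number 3 of 3 (chromosome 4, 74097772 to 74098600). CXCL2 expression rose by 4.52 on the log2 scale, and the authors' deposited table gave 6393 spliced reads for its intron after polarisation and 147 before. Other falls were those of P2RX1, an ATP receptor gene (0.289 ± 0.042 to 0.0822 ± 0.0098), and NFKBID, an NF-kB inhibitor gene (0.526 ± 0.030 to 0.323 ± 0.047; SD, n = 3 each). Other rises were those of RAB24 (0.265 ± 0.016 to 0.489 ± 0.031) and LZTR1 (0.387 ± 0.039 to 0.607 ± 0.035; SD, n = 3 each). They were chosen after their values were seen, by the same coverage limit. The 6 largest rises were in ITPR3, ICAM4, CPXM1, KPTN, FBXL8 and CHRNA10 and the 6 largest falls in IL13, ELF3, ACSM5, SCARF1, NOXA1 and DPEP2. Of the rises, ITPR3 had 10 and 25 spliced reads in polarised and resting macrophages in the authors' deposited table, CPXM1 178 and 11 and CHRNA10 6 and 16. ICAM4 had 187 and 97, KPTN 191 and 259 and FBXL8 96 and 158. Of the falls, the authors' deposited table gave only NOXA1 more than 20 spliced reads in both groups (79 and 183). Over 279 genes the change in retained fraction and in expression had a Spearman rho of 0.101 (permutation p = 0.0939, also after adjustment over 2 relations), which rose to 0.113 over all 3824 genes with a tested intron (permutation p = 1e-05, the smallest value possible).

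Knockdown of EXOSC10 raised the retained fraction of introns in the EXOSC10 gene itself, while most introns of the table were lower. Of the 1454 introns in the authors' deposited table, 647 were higher and 807 (55.5%, Wilson interval 52.9% to 58.0%) lower on knockdown. Introns 13, 15, 20, 21 and 24 of 24 of EXOSC10 were listed, and 5 of 5 were higher in the knockdown libraries. Intron 15 (chromosome 1, 11077444 to 11077600) was retained at 0.284 ± 0.029 after EXOSC10 siRNA and 0.0709 ± 0.020 after control siRNA (SD, n = 3 each; adjusted p = 2.83e-35 from the authors' deposited table). Spliced reads across the 5 introns were fewer in the knockdown, at a median ratio of 0.328 (0.275 to 0.426) in the authors' deposited table, while the median ratio over all listed introns was 0.964. The siRNA GAAGGCAGCUGAGCAAACA matches exon 20 of 25, in the coding sequence of EXOSC10 (chromosome 1, 11072088 to 11072106, minus strand, GRCh38), and no other annotated gene.

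No expression values per library were used for this experiment, so the spliced reads, which the authors' deposited table pools per group, are the measure of the target. At intron 15 they numbered 558 in the knockdown and 2027 in the control, and at intron 20 (11070974 to 11072086) 635 and 1935, per the authors' deposited table. Intron 20 was retained at 0.161 ± 0.034 and 0.0440 ± 0.0074, and intron 13 (11079823 to 11080498) at 0.125 ± 0.020 and 0.0354 ± 0.0147 (SD, n = 3 each). Of the 1454 introns 447 in 409 genes passed an adjusted p of 0.05, 219 higher and 228 lower on knockdown, with a median absolute difference of 0.0276. Only 69 of them (35 higher, 34 lower) reached a difference of 0.1 and a fraction of 0.1, and limma on the fractions of the libraries called 262 (101 higher, 161 lower), of which 111 were among the 447. With each of the 6 libraries left out in turn that fit called 80 to 139, the fewest without knockdown replicate A and the most without control replicate F. Higher and lower introns did not differ detectably in length (medians 181.0 and 169.5 bases, permutation p = 0.716) or GC content (56.2% and 57.8%, permutation p = 0.367), and both were shorter than introns not called (median 858.0 bases). Called introns had medians of 733 and 745 spliced reads in knockdown and control, against 262.5 and 285 over all listed introns, so coverage may enter that contrast.

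Among introns with at least 100 spliced reads in both groups, 1 in VPS9D1 (number 3 of 14, chromosome 16, 89716625 to 89716729) stood at 0.455 ± 0.153 on knockdown against 0.246 ± 0.048 (SD, n = 3 each). Another in MAP3K14, the NF-kB inducing kinase gene (number 15 of 15, chromosome 17, 45264801 to 45265162), stood at 0.297 ± 0.039 against 0.133 ± 0.074 (SD, n = 3 each). In the other direction 1 intron of EME1, a structure-specific endonuclease subunit (number 2 of 8, chromosome 17, 50375984 to 50376065), stood at 0.0997 ± 0.0192 against 0.254 ± 0.108 (SD, n = 3 each). That of GSAP, a gene of a gamma-secretase activating protein (number 29 of 30, chromosome 7, 77311941 to 77312100), stood at 0.0405 ± 0.0421 against 0.168 ± 0.021 (SD, n = 3 each). These 4 introns were chosen after their values were seen. All 4 are marked as overlapping a transcript of the other strand, as are introns 20 and 21 of EXOSC10, in the authors' deposited table, which was counted without strand, so reads of that transcript were not kept apart. The 6 largest rises by pooled fraction were in PSD2, MAP3K12, RAB26, AHNAK2, CCDC18 and CEMIP and the 6 largest falls in BCL2L15, EPS8L3, PRPF40B, KCNAB3, MYH10 and RAPGEF3, each with fewer than 100 spliced reads in both groups in the authors' deposited table.

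**Figure D3:**
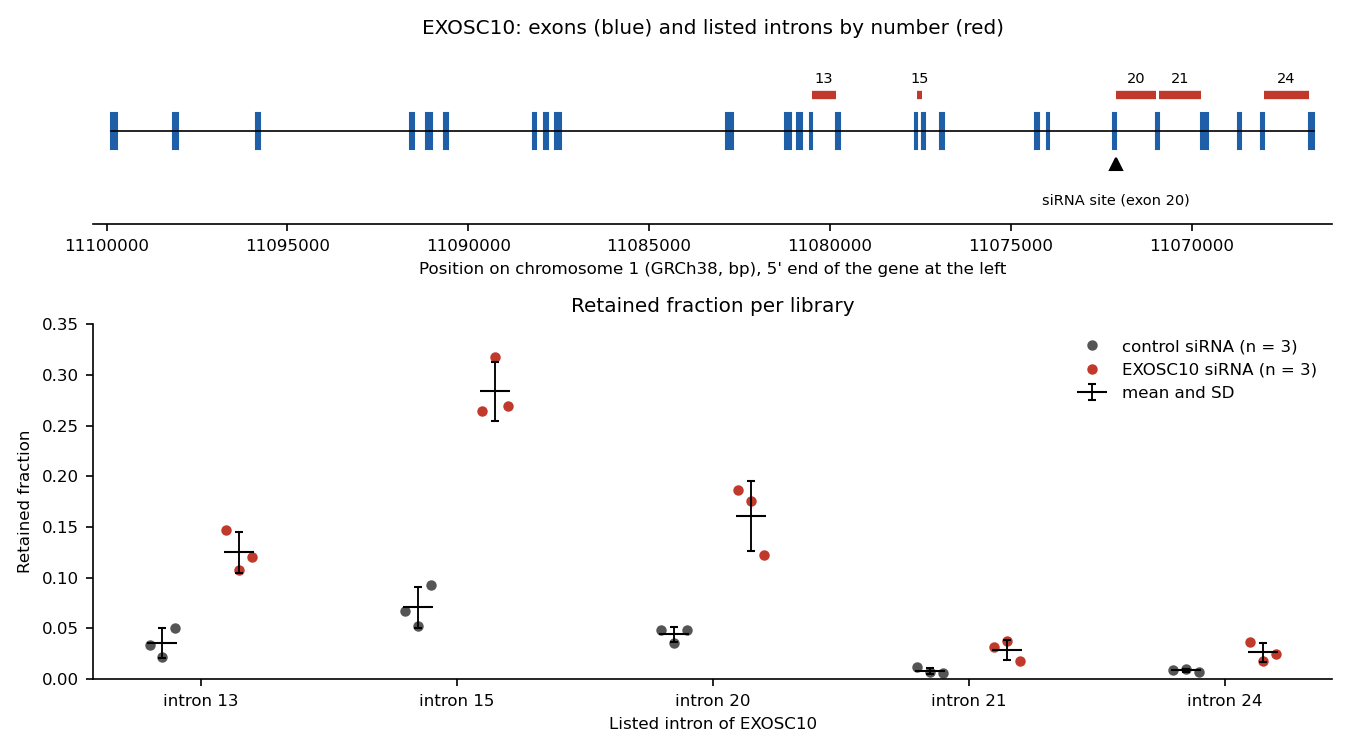
Top, the exons of EXOSC10 (blue) on chromosome 1 in GRCh38 coordinates, with the 5 listed introns in red and the siRNA site in exon 20; bottom, the retained fraction of each listed intron in the 3 control and 3 EXOSC10 siRNA libraries (points) with mean and SD (bars). In 5 of 5 introns every knockdown library lies above every control library. Only introns with separated groups were listed, so the lack of overlap was fixed by that selection and the direction was not.

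CpG methylation was compared between 1 monocytic and 1 macrophage bisulfite library, so the differences have no replicate check and the tests compare these libraries, not the conditions. Over 20643406 autosomal CpG sites with at least 10 reads in both, 69.1% of reads were methylated in macrophages (Wilson 95% interval 69.0749% to 69.0818%) and 70.0% in monocytic cells (70.0059% to 70.0128%), a difference of −0.931 percentage points. The mean over sites, which gives each site the same weight, differed by −0.189 points (70.0% against 70.2%). The coverage-weighted macrophage level was lower on 22 of 22 autosomes, by −0.510 to −1.85 points. Sites under 20% methylation made up 17.7% in macrophages and 17.6% in monocytic cells, sites over 80% made up 60.4% and 60.5%, and sites between them 21.9% and 21.8%.

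Few single sites were called at this coverage. Fisher's exact test called 28 sites with an adjusted p under 0.05 and a difference of at least 25 points, 22 of them lower in macrophages. With an upper coverage limit at the 99th percentile 11 sites were left (1 higher, 10 lower), and with a minimum of 20 reads 41 were called (10 higher, 31 lower). In the main analysis 783918 sites (3.80%) had an unadjusted p under 0.05. Of 262600 bins of 10 kb with at least 10 sites, 0 passed Fisher's exact test at an adjusted p of 0.05 with a difference of 20 points, and 0 bins had an unadjusted p under 0.05 at that size. At any size 15395 bins had an adjusted p under 0.05, 11658 of them lower in macrophages. A difference of 10 points was passed by 171 bins, 45 higher and 126 lower in macrophages. The largest of these rises, chosen after their values were seen and placed in the coordinates of the methylation file, whose build is not GRCh38, was on chromosome 6 (26920001 to 26930000), from 30.8% (61 of 198 reads over 12 sites) to 48.2% (108 of 224 reads). The largest falls were on chromosome 16 (32120001 to 32130000), from 78.0% (350 of 449 reads) to 58.8% (114 of 194 reads), and on chromosome 18 (15190001 to 15200000), from 74.3% (338 of 455 reads) to 55.9% (349 of 624 reads). No gene was assigned to these bins, since the annotation used here is on GRCh38.

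**Figure D4:**
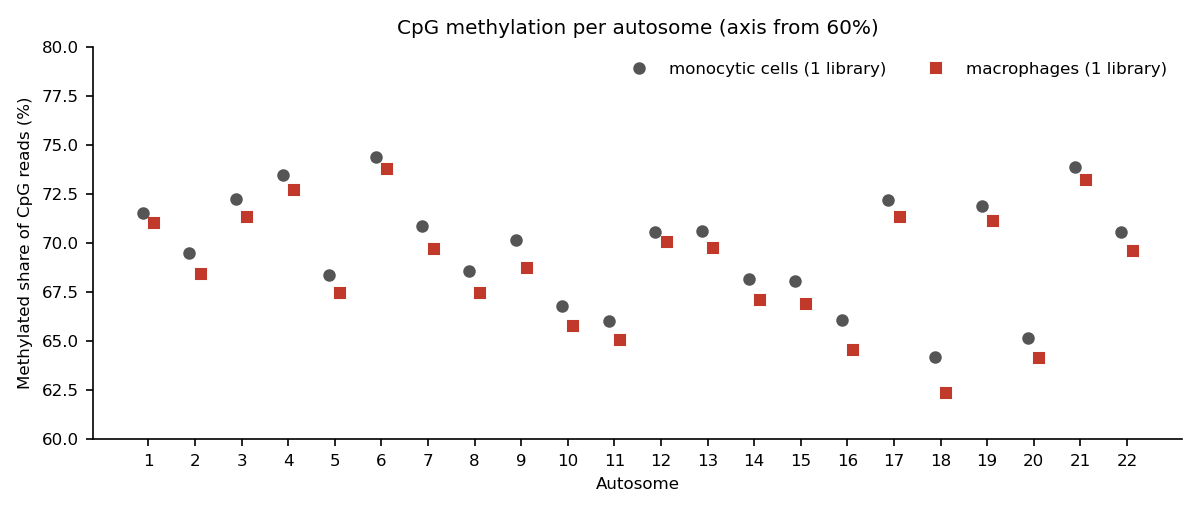
Share of methylated CpG reads per autosome (percent, axis from 60%) in the monocytic (circles) and macrophage (squares) bisulfite library, 1 each, at sites with at least 10 reads in both. The macrophage point is lower on 22 of 22 autosomes, by −0.510 to −1.85 percentage points, in levels weighted by coverage.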

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

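The test of bisulfite conversion on mitochondrial reads, both tests on the introns of EXOSC10 and the count of splits for genes were chosen after the result was seen.

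Reads at 439 mitochondrial CpG sites, which lie outside the autosomes that the report compares, were methylated above the level that counting error around 0 allows. The share was 8.39% (158414 of 1887371 reads, Wilson interval 8.35% to 8.43%) in the monocytic library and 9.37% (106057 of 1132329 reads, 9.31% to 9.42%) in the macrophage library. There is no control library, and nuclear copies of mitochondrial DNA or incomplete conversion were not separated from methylation.

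Autosomal CpG methylation differed by −0.931 points over all autosomes together, and the macrophage library was lower on 22 of 22 autosomes, by −0.510 to −1.85 points. These levels are weighted by coverage, and no mean over sites was taken per autosome. Less complete conversion in the monocytic library would raise its level, and the mitochondrial share was higher by 0.973 points in the macrophage library. That test cannot decide, since nuclear copies of mitochondrial DNA were not separated. Mitochondrial sites had 4299 reads on average in the monocytic and 2579 in the macrophage library, so methylated nuclear copies could weigh more in the latter at any conversion rate. At 987073 sites with the same coverage in both libraries the difference was −0.181 points, and the mean over sites differed by −0.189 points, so most of the coverage-weighted difference may come from how reads were spread over sites. The rest, a fraction of a point between 1 library and 1 library, stays open between differentiation, which was not tested with replicates, and preparation of the libraries.

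Most listed introns (73.2%) had a lower retained fraction in macrophages than in monocytic cells. A constant depth of background reads added to the monocytic libraries would weigh least where introns are deepest, yet among the 2136 introns with the highest mean depth 74.0% were lower. Unspliced background that grows with the expression of a gene would not weigh less there, so that test does not cover it. Over the listed introns the median ratio of intron depth, macrophages over monocytic cells, was 0.568, and that of spliced reads 1.005. Rising expression of the host genes is argued against by 77.5% among 2291 introns of genes with a log2 change under 0.25 in size, and thin coverage by 75.9% among 2918 introns without a warning and with at least 100 spliced reads in both groups. Open remain the authors' selection of introns, unspliced background that grows with expression, a bias by GC content, which was higher in called introns that fell (59.7%) than in those that rose (52.9%), and differentiation itself. None of these was tested, so a lower retention in macrophages is a hypothesis.

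The introns of EXOSC10 had a higher retained fraction in 5 of 5 listed cases after its knockdown. Spliced reads across the same introns had a median ratio of 0.328, under the 5th percentile of all listed introns (0.470). A candidate explanation for at least part of the rise is therefore the loss of spliced EXOSC10 transcripts by the siRNA, which would raise the fraction without a change in splicing. More intron-containing EXOSC10 RNA stays open. The median ratio of intron depth was 1.2201, above the median of all listed introns (0.807), and single introns spread too widely (5th to 95th percentile 0 to 4.23) for that test to decide. An effect of EXOSC10 on the decay of its own precursor RNA was not tested.

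For the genes and the gene lists that differed between macrophages and monocytic cells, the 10 splits of the 6 libraries are too few for a share under 0.05. The real split, 1 of the 10, gave 16409 genes and the highest of the others 0. For lists, 1 of the 10 splits, the real one, gave 22, and the others gave 16 to 21. Each of the other splits sets more monocytic libraries against fewer, and so keeps part of the group difference. The lists they passed therefore cannot show how often camera passes without a difference. With an estimated correlation 0 lists passed, so a pass at the preset correlation alone is weak evidence of a difference between the groups.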

How the results depend on the processing

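The alternatives with 9 or 7 columns, the replicate block with an estimated correlation, limma on retained fractions, doubled p-values and the knockdown size limit were chosen after the data were seen. Of 3122 values of named genes under the alternatives 2888 kept direction and side of the threshold, 231 lost the call and 3 reversed; of 1079 values of lists 957 kept both, 84 lost the call, 37 gained it and 1 reversed; of 228 values of named introns 171 kept both and 57 lost the call. The cause was not tested unless given.

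A log2 change of at least 1 left 6505 genes in macrophages against monocytic cells and 4074 in polarised against resting macrophages, by construction. With all 9 columns limma called 0 genes in the latter comparison (7534 at an unadjusted p under 0.05), where 1 column stands in both groups. Leaving out single libraries gave 15107 to 16925 and 10955 to 12278 genes. The replicate block gave 16041 and 12362 genes and 22 and 14 lists. In polarised against resting macrophages 1 list lost its call and 1 gained it with the block. With an estimated correlation 0 and 4 lists passed, with the replicate block as well 0 and 4, and fry passed 26 in polarised macrophages. In that comparison quantile normalisation reversed the hnRNP list (adjusted p = 0.402) and COX6C (−0.0131), RPS16 (−0.0136) and MT-CO1 (−0.47).

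With 9 columns the rise of cytokine (0.0732), NF-kB (0.214), IFN-γ target (0.27) and unfolded protein response genes (0.0815) in macrophages against monocytic cells no longer passed.

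Called introns in macrophages against monocytic cells numbered 1272 and 136 at differences of 0.05 and 0.2, 309 without warnings, 823 under limma, 800 with the replicate block and 648 to 807 with 1 library left out. For polarised macrophages they numbered 800, 79 and 222, and limma called 613, 572 with the replicate block and 496 to 544 with 1 library left out. For the knockdown 146 passed an adjusted p of 0.01, 283 a doubled p and 69 the size limit, and limma called 262, 116 with the replicate block and 80 to 139 with 1 library left out. Over all tested introns the correlation with expression was −0.0208 in macrophages, no longer past the threshold, and 0.113 in polarised macrophages, now past it with more genes.

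The methylation difference was −0.941, −0.871 and −0.857 points at coverage minimums of 5 and 20 and over all chromosomes, and −0.189 as a mean over sites, which weights sites equally. A minimum of 5 gave 4 bins and a difference of 10 points 171. At 32.1 and 32.8 reads per site on average 28 single sites passed, and whether depth or a lack of large differences limits that count was not tested. Promoter windows and methylation within introns were not run, since the builds differ, and tests on raw counts were not run for lack of counts.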

Other observations

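The comparison of the shares was chosen before its result was seen. The restriction to introns with an adjusted p under 0.05 in both tables, the count of introns called in both and the genes named were chosen after.

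Introns listed both in the knockdown table and in that of macrophages against monocytic cells numbered 270, in 256 genes. The hypothesis was that introns lower in macrophages are kept low by EXOSC10, so that they would be higher on knockdown more often. Of 189 introns lower in macrophages 110 (58.2%) were higher on knockdown, against 25 of 81 (30.9%) introns higher in macrophages (Fisher's exact p = 5.87e-05, two-sided, odds ratio 3.12), while 55.5% of all 1454 introns listed for the knockdown were lower. The difference between the shares may reflect decay of intron-containing RNA by EXOSC10, but among the 80 introns with an adjusted p under 0.05 in both tables the shares were 59.7% of 62 and 38.9% of 18 (Fisher's exact p = 0.178). EXOSC10 RNA was itself lower in macrophages (12.13 ± 0.08) than in monocytic cells (12.59 ± 0.14, log2 units, SD, n = 3 each). That reading therefore cannot rest on more EXOSC10 RNA in macrophages. Introns of one gene are not independent, and the table of the knockdown was counted without strand, which was not tested as a cause. Of 12 introns called in both, 11 were lower in macrophages. Of these, 5 were higher on knockdown (in HSF4, MIB2, OPLAH, RHPN1 and VPS9D1) and 6 lower, against the hypothesis (in ADCY6, GSDMD, MAN2C1, MAPK11, NRBP2 and SLC37A4).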
